A study of Homo sapiens with 32 samples.

How the data were processed

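Polyadenylated RNA from the human prostate cancer lines LNCaP and C4-2B was sequenced from 32 strand-specific libraries. The labels place them in 8 groups of 4 libraries, formed by line, by siRNA (control, siCTRL, or against MOCOS, siMOCOS) and by thapsigargin (TG) or none. The dose and time of TG are not given in the sources used here. The series describes the replicates as biological and the cells without TG as given vehicle.

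The authors' table holds 29744 genes. Its values are expected counts (estimated counts per gene, length-scaled per the file name) and were not divided by library size, since the deposited column totals differ. The submitters' processing notes name Trim Galore 0.6.7, cutadapt 3.4, FastQC 0.11.9, STAR 2.6.1d, Salmon 1.5.2 and the genome build hg38, without an order. The gene annotation behind the deposited table is not stated. Of the values above 0 in the table, 100% were not whole, so they were rounded before the count models. All 32 columns of values were used.

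The labels list 2 siRNAs against MOCOS, with 2 libraries of each per line and drug. The table numbers its knockdown columns within each line and drug without naming the siRNA, so no column could be assigned to an siRNA. The plan made before the data were examined had treated each siRNA as a group of its own, 6 groups per line, and had asked for genes called with each siRNA. That part could not be computed. The 4 knockdown libraries of a line and drug were pooled as 1 group instead, which leaves 4 groups per line and 12 residual degrees of freedom. The p-values thus treat libraries of 2 siRNAs as replicates. A replicate number of a knockdown library is the number of its column.

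Each line was fitted alone with edgeR 4.0.16 under R 4.3.3, with filterByExpr by group, TMM factors, estimateDisp, and the quasi-likelihood F-test (glmQLFit, glmQLFTest). P-values were adjusted over genes by the Benjamini-Hochberg procedure, and a gene was called at an adjusted p under 0.05. The filter left 14127 genes in C4-2B and 13806 in LNCaP, and the biological coefficient of variation was 0.219 and 0.174. Differences between the lines came from 1 fit of all 32 libraries and 14628 genes, with 24 residual degrees of freedom. Every adjusted p of a gene in the text comes from this edgeR test unless another tool is named. Levels are in CPM, counts scaled to a common library size with the TMM factors, as mean and SD over the libraries of a group. Some log2 fold changes of genes are given with a standard error (SE). It was derived as the absolute unshrunken log2 change divided by the square root of F. The printed log2 change is the shrunken value of the same test.

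Within each line the comparisons were TG in siCTRL cells, knockdown without TG, knockdown with TG, TG in knockdown cells, and their interaction, which is the knockdown effect with TG minus that without. Between the lines, LNCaP minus C4-2B was tested for siCTRL cells without TG, for the TG response, and for the knockdown response without and with TG.

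Gene lists were written from general knowledge before the data were examined, with MOCOS left out of all of them. They cover XBP1s, ATF6 and PERK-ATF4-CHOP targets, purine catabolism with the molybdenum cofactor, purine salvage, purine de novo synthesis, pyrimidine synthesis and catabolism, androgen receptor targets, G1/S and DNA replication, G2/M and mitosis, p53 targets, NRF2 targets, cholesterol synthesis, interferon response, hypoxia and glycolysis, cytosolic heat shock, autophagy and lysosome, nuclear oxidative phosphorylation, mitochondrially encoded transcripts, cytosolic ribosomal proteins, luminal epithelium, basal and mesenchymal markers, neuroendocrine markers, and immune, stromal, endothelial and blood markers. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, where at least 3 members were measured. Each test was repeated with a correlation estimated from the data. Counts of called members are given over all genes and adjusted over the list alone. No member of the list of mitochondrially encoded transcripts was measured under the symbols searched.

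Named genes follow a rule set before the data were examined. It takes MOCOS, XDH and AOX1 throughout, then the 5 genes with the greatest rise and the 5 with the greatest fall in each comparison within a line, among called genes with a mean of at least 5 CPM and no overlap between the libraries of the sides. For interactions and line differences it takes the 3 greatest in each direction without the overlap condition. It also takes the 3 called members with the smallest adjusted p from the lists of the unfolded protein response and purine catabolism, and from up to 6 other called lists. The condition that a knockdown gene be called with each siRNA could not be applied. The text names only some of the genes that the rule takes, and these were picked after their values were seen. Genes with near-identical copies, whose reads the counting could split, were not named. Positions are on GRCh38.

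Library totals ran from 7507154 to 27088375 counts. Intervals and bounds cover counting error only. Where a gene had 0 counts over a group, its fold was computed against 3 counts over the group and is a lower bound. The smallest chi-square per degree of freedom between a pair of libraries of the same group was 4.956, so none of these pairs were copies, and libraries of different groups were not compared in this way. Replicate numbers of the siCTRL libraries showed no sign of pairing a TG library with an untreated library. The correlation of deviations was highest at the same number for 1 of 4 numbers in LNCaP and for 0 of 4 in C4-2B. Trends with transcript length can decide these matches, so the check cannot exclude a pairing. C4-2B siCTRL replicate 2 matched TG replicate 3 best (0.502), and their deviations correlated with length at 0.525 and 0.529.

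The design was tested on simulated data with known changes. For changes of 2-fold, 44.8% to 79.1% of changed genes were called across the comparisons within a line other than the interactions, and 28.4% and 46.3% in the interactions of C4-2B and LNCaP. For 4-fold changes the interactions recovered 77.3% and 78.8%, and for 1.5-fold changes 1.49% and 8.96%. No simulated list without a change was called. The simulated genes varied independently, without trends in GC content or length and without differences among the knockdown columns. This check thus cannot show how often camera calls a list whose members vary together. For ribosomal proteins with TG in C4-2B siCTRL cells the estimated correlation was 0.541.

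The alternatives planned were DESeq2 1.42.0, limma voom, RLE factors in place of TMM, no filter on low counts, no rounding, all libraries of both lines in 1 fit, only the libraries compared, the replicate number as a block, a minimum change of 1 log2 unit, an estimated correlation for the lists, and each library left out in turn. GC content was the median, and length the longest, over the annotated transcripts of a gene symbol. A correction of each library for GC content and transcript length (mgcv 1.9.3, for the 89.1% of tested genes where both were known) was added after the data were seen. So was a fit without 3 libraries that stand apart, those whose deviations from their group mean correlated with transcript length across genes above 0.45, a threshold also chosen then. It took positive correlations alone, and 3 siCTRL libraries below -0.45 were left out only in turn. Other splits of the libraries were fitted, all 35 where 4 libraries face 4 and 50 drawn with a fixed seed for the interactions and the line differences in response. The plots were drawn with matplotlib 3.10.9.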

Results

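RNA-seq was used to ask how ER stress and loss of MOCOS change the transcriptome of LNCaP, an androgen-sensitive human prostate cancer line, and C4-2B, a castration-resistant line derived from it. MOCOS is the molybdenum cofactor sulfurase, which completes the cofactor of xanthine dehydrogenase (XDH) and aldehyde oxidase (AOX1). Thapsigargin (TG) blocks the SERCA calcium pump, empties the ER of calcium and so causes ER stress. The 32 libraries formed 8 groups of 4, siCTRL and siMOCOS cells of each line with and without TG. In C4-2B the totals were 12.4 to 18.4 M counts per library in siCTRL, 14.3 to 24.4 M in siCTRL with TG, 17.3 to 19 M in siMOCOS, and 18 to 22.2 M in siMOCOS with TG. In LNCaP they were 12.1 to 19.9 M, 11.7 to 20.3 M, 7.51 to 15.7 M, and 18.9 to 27.1 M in the same order. The knockdown columns do not name which of the 2 siRNAs they hold, so the 4 knockdown libraries of a group were pooled and nothing is reported per siRNA.

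MOCOS (chromosome 18, 36187519 to 36272157, plus strand) was lower in every knockdown library than in any siCTRL library of the same line and drug. In C4-2B its level was 33.1 ± 2.32 CPM (SD, n = 4) in siCTRL and 3.57 ± 1.11 CPM (SD, n = 4) in siMOCOS, a log2 change of -3.20 (SE 0.221, adjusted p = 4.48e-08). In LNCaP it was 23.1 ± 0.670 against 3.51 ± 0.263 CPM (SD, n = 4 each), a log2 change of -2.72 (SE 0.174, adjusted p = 5.18e-08). TG raised MOCOS in siCTRL cells to 93.6 ± 2.89 CPM in C4-2B (log2 1.5, SE 0.198, adjusted p = 1.47e-05) and to 91.4 ± 4.19 CPM in LNCaP (log2 1.98, SE 0.149, adjusted p = 8.22e-09). With TG the knockdown changed it by log2 -2.57 (SE 0.206, adjusted p = 1.98e-07) in C4-2B and -2.72 (SE 0.153, adjusted p = 6.29e-09) in LNCaP. TG also raised MOCOS in knockdown cells, to 15.7 ± 4.56 CPM in C4-2B (log2 2.14, adjusted p = 8.19e-07) and 13.8 ± 3.99 CPM in LNCaP (log2 1.98, adjusted p = 5.13e-08). The interaction of knockdown and TG was not called for MOCOS in C4-2B (log2 0.64, adjusted p = 0.663) or LNCaP (log2 -0.01, adjusted p = 1).

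XDH (chromosome 2, 31334321 to 31414715, minus strand), which oxidises hypoxanthine and xanthine to uric acid, rose with TG in siCTRL cells of both lines. It went from 1.91 ± 0.239 to 18.2 ± 2.02 CPM (SD, n = 4 each) in C4-2B (log2 3.24, SE 0.206, adjusted p = 7.03e-09). In LNCaP it went from 4.42 ± 0.522 to 30.1 ± 1.28 CPM (SD, n = 4 each; log2 2.76, SE 0.15, adjusted p = 1.74e-10). Knockdown of MOCOS raised XDH in C4-2B, to 4.83 ± 1.47 CPM without TG (log2 1.33, SE 0.206, adjusted p = 0.000186) and to 29.5 ± 1.21 CPM with TG (log2 0.70, SE 0.175, adjusted p = 0.00969). In LNCaP the knockdown effect on XDH was not called without TG (log2 -0.26, adjusted p = 0.292) or with TG (log2 0.02, adjusted p = 0.913). AOX1 stayed low, at 0.115 CPM in C4-2B siCTRL and 0.542 CPM with TG. Its change there (log2 2.08, adjusted p = 0.0235) was no longer called without siCTRL replicate 2 (0.0551) or 3 (0.0509), or without siCTRL TG replicate 1 (0.0538) or 4 (0.0576). After knockdown AOX1 was called higher in C4-2B without TG (log2 2.21, adjusted p = 0.0335), but not with limma voom (0.112) or without siCTRL replicates 1 to 4 (0.0543, 0.0791, 0.073 and 0.0594) or siMOCOS replicates 1 (0.122) or 2 (0.0881). In LNCaP it was called higher after knockdown with TG (log2 1.30, adjusted p = 0.0218), but not without siCTRL TG replicates 3 (0.0758) or 4 (0.0742) or siMOCOS TG replicates 2 (0.0505) or 3 (0.0692). TG raised AOX1 in LNCaP knockdown cells (log2 1.63, adjusted p = 0.00389). SUOX, sulfite oxidase, whose molybdenum cofactor does not need MOCOS, fell with TG from 68.2 ± 7.23 to 30.2 ± 3.21 CPM in C4-2B (log2 -1.17, adjusted p = 2.09e-06). In LNCaP it fell from 68.5 ± 5.18 to 19.9 ± 3.16 CPM (log2 -1.79, adjusted p = 8.45e-09). AMPD2, an AMP deaminase, rose in LNCaP after knockdown without TG (log2 0.51, adjusted p = 0.00982) and with TG (log2 0.67, adjusted p = 0.00108), the former not called when all libraries of both lines were fitted together (0.0629).

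As a list, the 16 measured genes of purine catabolism and the molybdenum cofactor were not called by camera in any comparison within a line. With TG in siCTRL cells 3 rose and 3 fell in C4-2B (3 and 3 adjusted over the list alone, adjusted p = 0.791), where the list median was -0.149 and its mean 0.108. In LNCaP 3 rose and 5 fell (3 and 5 adjusted over the list alone, adjusted p = 0.773). With knockdown without TG the adjusted p was 0.46 in C4-2B and 0.541 in LNCaP.

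**Figure D1:**
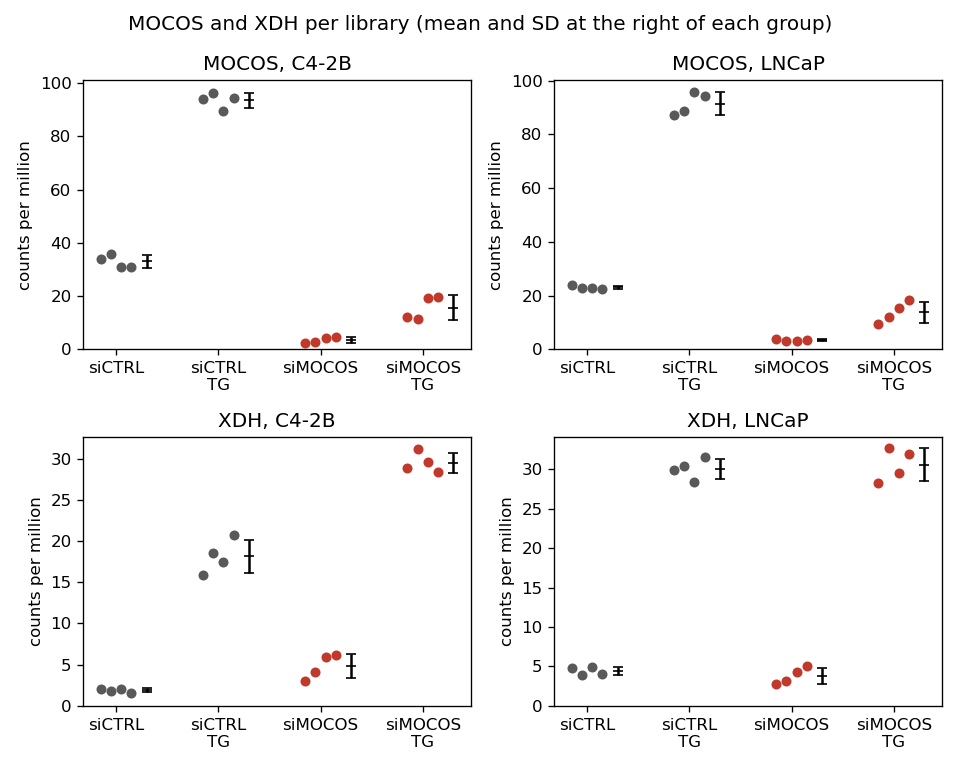
Level per library of MOCOS (top) and XDH (bottom), in CPM, for the 4 groups of C4-2B (left) and LNCaP (right), with the mean and SD of each group of 4 at the right of its points. In C4-2B the MOCOS libraries with TG span 89.6 to 96.4 CPM in siCTRL and 11.3 to 19.8 CPM in knockdown.

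Targets of the unfolded protein response rose with TG in siCTRL cells of both lines. Of the 32 measured XBP1s targets, which serve secretion and ER-associated degradation, 27 rose in C4-2B and 26 in LNCaP (27 and 26 adjusted over the list alone), and none fell. DNAJB9, an ER co-chaperone, went from 52.6 ± 7.65 to 254 ± 12.1 CPM in C4-2B (log2 2.27, SE 0.117, adjusted p = 7.32e-10). In LNCaP it went from 47.2 ± 4.50 to 304 ± 22.8 CPM (SD, n = 4 each; log2 2.68, SE 0.0986, adjusted p = 2.21e-12). Of the 37 PERK-ATF4-CHOP targets, 30 rose in C4-2B (31 adjusted over the list alone) and 33 in LNCaP (33 adjusted over the list alone). TRIB3, a pseudokinase induced by ATF4 and CHOP, rose from 28.4 ± 3.95 to 136 ± 25.1 CPM in C4-2B (log2 2.26, adjusted p = 7.03e-09) and from 24.1 ± 3.23 to 158 ± 23.6 CPM in LNCaP (log2 2.71, adjusted p = 2.76e-11). Of the 15 ATF6 targets, 8 rose in C4-2B and 11 in LNCaP (8 and 11 adjusted over the list alone). Among them HSPA5, the ER chaperone BiP, went from 2625 ± 266 to 5437 ± 770 CPM in C4-2B (log2 1.05, adjusted p = 8.59e-05) and from 2496 ± 202 to 7333 ± 535 CPM in LNCaP (log2 1.56, adjusted p = 2.99e-08). Camera called the XBP1s list (adjusted p = 1.2e-12 in C4-2B, 8.48e-16 in LNCaP), the PERK list (6.62e-22, 4.68e-29) and the ATF6 list (0.00309, 0.000146). For XBP1s this was adjusted p = 0.0489 with an estimated correlation in C4-2B and adjusted p = 0.0699 with an estimated correlation in LNCaP, for PERK 0.0467 and 0.00144, and for ATF6 0.293 and 0.282.

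The keratin gene KRT80 had one of the greatest changes with TG, from 0.540 ± 0.171 to 58.8 ± 4.77 CPM in C4-2B (log2 6.73, SE 0.367, adjusted p = 1.22e-09) and from 0.282 ± 0.192 to 33.2 ± 5.54 CPM in LNCaP (log2 6.91, SE 0.289, adjusted p = 5.81e-12; SD, n = 4 each). The noncoding RNA LINC00346 rose by log2 6.32 in C4-2B (adjusted p = 4.55e-08) and 6.30 in LNCaP (adjusted p = 4.38e-10). VAV3, a guanine nucleotide exchange factor, rose in C4-2B from 0.405 ± 0.148 to 14.3 ± 0.953 CPM (log2 5.12, adjusted p = 1.73e-07). TNFRSF9, a receptor of the TNF family, rose in LNCaP from 0.112 ± 0.0402 to 12.4 ± 0.771 CPM (log2 6.65, adjusted p = 4.8e-09). NRARP, a Notch target, fell in C4-2B from 18.5 ± 1.12 to 1.82 ± 0.332 CPM (log2 -3.34, adjusted p = 1.59e-07). WNT7B, a Wnt ligand, fell by log2 -3.04 in C4-2B (adjusted p = 3.34e-05) and -3.60 in LNCaP (adjusted p = 1.28e-06). OR51E1, an olfactory receptor expressed in prostate, fell in LNCaP from 48.8 ± 10.00 to 2.62 ± 0.182 CPM (log2 -4.21, adjusted p = 2.54e-10).

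Many androgen receptor targets, heat shock genes, ribosomal protein genes and genes of oxidative phosphorylation fell with TG. Of 24 androgen receptor targets, 14 fell and 2 rose in C4-2B (16 and 3 adjusted over the list alone), and 17 fell and 2 rose in LNCaP (18 and 2 adjusted over the list alone). TMPRSS2, a serine protease gene induced by androgen, fell from 389 ± 8.93 to 95.0 ± 6.45 CPM in C4-2B (log2 -2.03, adjusted p = 1.69e-08) and from 578 ± 22.2 to 73.4 ± 8.50 CPM in LNCaP (log2 -2.98, adjusted p = 2.21e-12). KLK3, which encodes prostate-specific antigen, fell in LNCaP from 1469 ± 161 to 335 ± 39.4 CPM (log2 -2.13, adjusted p = 4.79e-09). Of 16 cytosolic heat shock genes, 9 fell in C4-2B (10 adjusted over the list alone), and 10 fell and 1 rose in LNCaP (10 and 1 adjusted over the list alone). HSPA8, the constitutive HSP70, went from 3697 ± 427 to 864 ± 49.2 CPM in C4-2B (log2 -2.10, adjusted p = 1.08e-08) and from 4369 ± 269 to 1304 ± 112 CPM in LNCaP (log2 -1.74, adjusted p = 4.12e-09). Of 77 ribosomal protein genes, 61 fell in C4-2B and 69 in LNCaP (71 and 71 adjusted over the list alone). Of 35 nuclear genes of oxidative phosphorylation, 26 fell in C4-2B and 25 in LNCaP (28 and 27 adjusted over the list alone).

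For these lists camera gave an adjusted p in C4-2B and LNCaP of 8.36e-05 and 3.92e-09 (androgen receptor targets), 1.38e-06 and 2.48e-05 (heat shock), 4.58e-13 and 5.3e-11 (ribosomal proteins), and 1.18e-06 and 5.66e-05 (oxidative phosphorylation). In the same order it was adjusted p = 0.102 with an estimated correlation in C4-2B and 0.0209 in LNCaP, then 0.00315 and 0.0209, 0.242 and 0.282, and 0.26 and 0.282. In C4-2B siCTRL replicate 2, C4-2B siCTRL TG replicate 3 and LNCaP siCTRL TG replicate 4, the deviation of genes from their group mean correlated with transcript length across genes (0.525, 0.529 and 0.468). It correlated as strongly in the other direction in C4-2B siCTRL replicate 4, C4-2B siCTRL TG replicate 2 and LNCaP siCTRL TG replicate 2 (-0.521, -0.549 and -0.457), and genes are not independent replicates. With GC content the strongest correlation was -0.712, in C4-2B siCTRL replicate 1, which is not among the libraries taken to stand apart. Among others it was 0.586 in C4-2B siCTRL replicate 4 and 0.542 in LNCaP siCTRL TG replicate 2.

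Some cell cycle genes were lower with TG as well, and with an estimated correlation camera called only G1/S in C4-2B. Of 24 G1/S genes, 12 fell and 1 rose in C4-2B (13 and 1 adjusted over the list alone), and 15 fell and 1 rose in LNCaP (15 and 1 adjusted over the list alone). Of 24 G2/M genes, 9 fell in C4-2B and 14 in LNCaP (9 and 15 adjusted over the list alone). UHRF1, which maintains DNA methylation at replication, fell by log2 -2.28 in C4-2B (adjusted p = 4.55e-08) and -2.04 in LNCaP (adjusted p = 4.45e-09). CDC6, a replication licensing factor, went the other way, from 88.4 ± 10.5 to 257 ± 28.5 CPM in C4-2B (log2 1.54, adjusted p = 6.2e-07) and from 80.9 ± 8.83 to 173 ± 2.11 CPM in LNCaP (log2 1.10, adjusted p = 1.82e-08). For G1/S the camera adjusted p was 0.000797 in C4-2B and 0.000108 in LNCaP, with adjusted p = 0.0179 with an estimated correlation and 0.282 likewise. For G2/M it was 0.00144 and 0.000184, with adjusted p = 0.183 with an estimated correlation and 0.294 likewise. In all, edgeR called 2998 genes higher and 2727 lower with TG in C4-2B, and 3394 higher and 3467 lower in LNCaP. Of the 13458 genes tested in both lines, 2334 rose in both and 2172 fell in both, against 707 and 675 if the calls were independent, and 13 were called in opposite directions. Genes with more counts are called more readily in any comparison, so independence here and below is only a reference.

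Knockdown of MOCOS without TG lowered cell cycle genes in both lines. Of 24 G2/M genes, 24 fell in C4-2B and 24 in LNCaP (24 and 24 adjusted over the list alone). Of 24 G1/S genes, 22 fell in C4-2B and 21 in LNCaP (23 and 24 adjusted over the list alone). KIF20A, a mitotic kinesin, went from 137 ± 10.4 to 25.1 ± 8.54 CPM in C4-2B (log2 -2.44, SE 0.252, adjusted p = 2.5e-06) and from 63.4 ± 4.44 to 15.2 ± 3.93 CPM in LNCaP (log2 -2.07, SE 0.173, adjusted p = 1.02e-06; SD, n = 4 each). In C4-2B, AURKB, a mitotic kinase, fell by log2 -2.29 (adjusted p = 9.36e-08), MCM7, a subunit of the replicative helicase, by log2 -1.58 (adjusted p = 8.17e-08) and TYMS, thymidylate synthase, by log2 -1.75 (adjusted p = 8.87e-08). In LNCaP, CCNA2, which encodes cyclin A2, fell by log2 -1.74 (adjusted p = 1.63e-07), CDC6 by log2 -1.73 (adjusted p = 5.18e-09) and ESCO2, a cohesin acetyltransferase, by log2 -2.09 (adjusted p = 1.43e-05). Camera gave an adjusted p of 5.92e-66 and 8.18e-54 for G2/M and 2.02e-48 and 5.79e-34 for G1/S, in C4-2B and LNCaP. With an estimated correlation the adjusted p was 3.2e-06 and 0.00175 for G2/M and 5.66e-08 and 0.00747 for G1/S.

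Some interferon response genes and PERK targets were lower after knockdown without TG too, and camera called both lists lower only at the preset correlation. Of 25 interferon response genes measured in C4-2B, 8 fell (8 adjusted over the list alone), and of 26 in LNCaP, 9 fell (12 adjusted over the list alone). USP18, a negative regulator of interferon signalling, fell by log2 -0.98 in C4-2B (adjusted p = 0.00037) and -0.90 in LNCaP (adjusted p = 0.000712). The camera adjusted p was 0.00583 and 0.000355, with adjusted p = 0.0856 with an estimated correlation and 0.104 likewise. Of 37 PERK-ATF4-CHOP targets, 15 fell in C4-2B and 8 in LNCaP (20 lower and 2 higher, and 8 lower and 1 higher, adjusted over the list alone). The camera adjusted p was 1.32e-06 and 0.00872, with adjusted p = 0.184 with an estimated correlation and 0.373 likewise. TRIB3 fell by log2 -0.95 in C4-2B (adjusted p = 0.000137) and -0.67 in LNCaP (adjusted p = 0.00193), and HSPA5 fell in LNCaP from 2496 ± 202 to 1419 ± 262 CPM (log2 -0.81, adjusted p = 0.000319). Of 32 XBP1s targets, 10 fell in LNCaP (16 adjusted over the list alone; adjusted p = 0.000782, and adjusted p = 0.428 with an estimated correlation). Of 15 ATF6 targets 2 fell there (2 adjusted over the list alone; adjusted p = 0.0434, and adjusted p = 0.586 with an estimated correlation), a call lost with the GC and length correction (0.0571) and without siCTRL replicate 1 or 2 (0.0714 each) or siMOCOS replicate 1 (0.235) or 2 (0.167). The knockdown libraries were not alike in these lists. Around a mean change of -0.283 for XBP1s in LNCaP, siMOCOS replicates 1 to 4 deviated by -0.165, -0.276, 0.187 and 0.254 from their group mean, around -0.225 for ATF6 by -0.277, -0.34, 0.314 and 0.303, and around -0.503 for PERK in C4-2B by -0.283, -0.273, 0.26 and 0.296.

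In C4-2B, 6 of 14 luminal epithelium genes rose after knockdown without TG (7 adjusted over the list alone; adjusted p = 0.000566, and adjusted p = 0.0105 with an estimated correlation), among them STEAP2, a metalloreductase (log2 0.78, adjusted p = 0.000529). TMPRSS2 rose there from 389 ± 8.93 to 796 ± 158 CPM (log2 1.03, adjusted p = 3.43e-05; SD, n = 4 each). Androgen receptor targets were called in C4-2B, with 8 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0071, and adjusted p = 0.184 with an estimated correlation). CROT, a peroxisomal carnitine acyltransferase, rose in C4-2B from 10.4 ± 2.22 to 72.8 ± 35.8 CPM (log2 2.80, adjusted p = 1.53e-05), and F5, which encodes coagulation factor V, rose in LNCaP from 8.93 ± 0.686 to 49.8 ± 19.0 CPM (log2 2.48, adjusted p = 9.14e-06). In all, edgeR called 1284 genes higher and 1150 lower in C4-2B. In LNCaP it called 829 higher and 1344 lower, where DESeq2 gave 1258 and 1329, the fit corrected for GC content and length 1133 and 1016, and the fit without the libraries that stand apart 1132 and 1080. Without LNCaP siMOCOS replicate 2 the LNCaP count of 2173 dropped to 1392. Across the lines, 395 genes rose and 690 fell in both, against 73.7 and 112 if independent, and 0 were called in opposite directions.

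Further lists were called after knockdown without TG, each lost with an estimated correlation. Of 20 p53 targets 7 rose in C4-2B (7 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.122 with an estimated correlation). In LNCaP 5 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00368, and adjusted p = 0.19 with an estimated correlation). Of 4 measured immune, stromal, endothelial and blood markers 2 rose in LNCaP (3 adjusted over the list alone; adjusted p = 0.00751, and adjusted p = 0.19 with an estimated correlation), and the call was lost without a filter on low counts (0.0791). In C4-2B the list was not called (adjusted p = 0.0557). With TG 2 of these markers rose in LNCaP (3 adjusted over the list alone; adjusted p = 0.0345, and adjusted p = 0.232 with an estimated correlation), a call lost without siCTRL TG replicates 2 (0.0554), 3 (0.0537) or 4 (0.0511) or siMOCOS TG replicates 1 (0.0591) or 2 (0.0603). Of 19 cholesterol synthesis genes 4 fell and 2 rose in C4-2B (7 and 2 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.161 with an estimated correlation), a call lost without siCTRL replicate 1 (0.0547). Of 24 hypoxia and glycolysis genes 4 fell in C4-2B and 5 in LNCaP (7 and 5 adjusted over the list alone; adjusted p = 0.0071 and 0.00682), with adjusted p = 0.184 with an estimated correlation and 0.428 likewise. Of 12 genes of purine de novo synthesis 5 fell in C4-2B and 5 in LNCaP (7 and 6 adjusted over the list alone; adjusted p = 0.0386 and 0.00682), with adjusted p = 0.122 with an estimated correlation and 0.0539 likewise. The C4-2B call was lost without siCTRL replicate 1 (0.103) or siMOCOS replicate 4 (0.0566).

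With TG present, knockdown again lowered most genes of the G2/M and G1/S lists and some interferon response genes. Of 24 G2/M genes, 24 fell in C4-2B and 24 in LNCaP (24 and 24 adjusted over the list alone). Of 24 G1/S genes, 21 fell in C4-2B and 19 in LNCaP (21 and 22 adjusted over the list alone). CLSPN, a replication checkpoint mediator, fell from 63.0 ± 17.9 to 9.72 ± 2.86 CPM in C4-2B (log2 -2.69, SE 0.229, adjusted p = 3.77e-07) and from 46.4 ± 6.56 to 10.7 ± 0.303 CPM in LNCaP (log2 -2.11, SE 0.186, adjusted p = 8.18e-07; SD, n = 4 each). Of the interferon response genes, 9 of 25 fell in C4-2B and 10 of 26 in LNCaP (10 and 13 adjusted over the list alone). OASL, of the oligoadenylate synthetase family, fell by log2 -1.91 in C4-2B (adjusted p = 4.01e-06), and DDX60, an interferon-induced helicase, by log2 -1.23 in LNCaP (adjusted p = 0.000106). SMIM15, a small membrane protein gene, rose from 15.7 ± 0.758 to 94.4 ± 9.95 CPM in C4-2B (log2 2.59, adjusted p = 1.03e-08) and from 16.9 ± 3.16 to 72.1 ± 3.31 CPM in LNCaP (log2 2.09, adjusted p = 3.21e-08). GNG5, a G protein gamma subunit, rose by log2 2.47 in C4-2B (adjusted p = 1.11e-07) and 1.99 in LNCaP (adjusted p = 6.25e-08). In C4-2B, 6 of 14 luminal epithelium genes rose and 1 fell (8 and 1 adjusted over the list alone), with FOXA1, a pioneer factor of the androgen receptor, at 265 ± 25.2 against 535 ± 27.7 CPM (log2 1.01, adjusted p = 6.53e-06).

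For knockdown with TG camera gave an adjusted p in C4-2B and LNCaP of 5.64e-48 and 3.22e-37 for G2/M, 9.59e-42 and 4.59e-22 for G1/S, and 8.57e-05 and 1e-04 for interferon response. In LNCaP this was adjusted p = 0.0149 with an estimated correlation for G2/M, 0.0508 for G1/S and 0.0919 for interferon response, and in C4-2B 2.63e-05, 7.35e-08 and 0.0184. The luminal list in C4-2B had adjusted p = 0.000152, and adjusted p = 0.00648 with an estimated correlation. In C4-2B, 8 of 32 XBP1s targets rose (12 adjusted over the list alone), with adjusted p = 0.000152, and adjusted p = 0.295 with an estimated correlation. Of 15 ATF6 targets 3 rose there (3 adjusted over the list alone), with adjusted p = 0.0177, and adjusted p = 0.56 with an estimated correlation. The ATF6 call was lost without C4-2B siCTRL TG replicate 3 (0.0616) and without C4-2B siMOCOS TG replicate 1 (0.0679). In all, edgeR called 1301 genes higher and 1074 lower in C4-2B. In LNCaP it called 1615 higher and 1410 lower, against 938 and 1139 without the libraries that stand apart. The LNCaP count of 3025 dropped to 1980 without siCTRL TG replicate 3 and to 1925 without siMOCOS TG replicate 1. Across the lines 517 genes rose and 647 fell in both, against 148 and 109 if independent, and 3 were called in opposite directions. Within C4-2B 669 genes rose and 708 fell with knockdown both without and with TG (118 and 87.4 if independent), and within LNCaP 532 and 835 (97 and 137 if independent). Comparisons within a line also share the dispersion of each gene, which adds to shared calls.

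In knockdown cells TG again raised targets of the unfolded protein response. Of 32 XBP1s targets, 27 rose in C4-2B and 29 in LNCaP (28 and 29 adjusted over the list alone). Of 37 PERK-ATF4-CHOP targets, 33 and 34 rose (33 and 35 adjusted over the list alone), and of 15 ATF6 targets, 11 and 13 (13 and 13 adjusted over the list alone). HSPA5 went from 1803 ± 124 to 6490 ± 1839 CPM in C4-2B (log2 1.85, adjusted p = 2.89e-07) and from 1419 ± 262 to 5780 ± 900 CPM in LNCaP (log2 2.03, adjusted p = 1.41e-09; SD, n = 4 each). LAMP3, a lysosome-associated membrane protein, rose in C4-2B from 0.268 ± 0.194 to 20.6 ± 1.21 CPM (log2 6.23, adjusted p = 3.77e-09). Of 19 cholesterol synthesis genes, 10 rose and 1 fell in C4-2B (11 and 1 adjusted over the list alone), and 14 rose in LNCaP (15 adjusted over the list alone). STARD4, a sterol carrier, rose by log2 1.75 (adjusted p = 1.74e-07) and 1.55 (adjusted p = 4.35e-09). TMPRSS2 fell by log2 -2.60 in C4-2B (adjusted p = 1.18e-09) and -2.90 in LNCaP (adjusted p = 2.26e-12), and of the androgen receptor targets 16 fell and 2 rose in C4-2B (16 and 3 adjusted over the list alone), and 17 fell and 2 rose in LNCaP (17 and 2 adjusted over the list alone).

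In the camera test of TG in knockdown cells the adjusted p in C4-2B and LNCaP was 1.96e-25 and 3.17e-23 for XBP1s, 1.78e-34 and 8.03e-34 for PERK, 6.72e-08 and 2.12e-07 for ATF6, 0.00565 and 0.000266 for cholesterol synthesis, and 1.88e-06 and 7.87e-10 for androgen receptor targets. In the order ATF6, cholesterol synthesis and androgen receptor targets it was adjusted p = 0.102 with an estimated correlation in C4-2B and 0.147 in LNCaP, then 0.0892 and 0.0713, and 0.0591 and 0.0164. For XBP1s it was 0.00533 and 0.0288, and for PERK 0.00533 and 0.000572. In all, 2926 genes rose and 2434 fell in C4-2B, and 3463 and 3022 in LNCaP. In C4-2B 2264 rose and 1880 fell with TG in both siCTRL and knockdown cells (621 and 470 if independent, 8 opposite), and in LNCaP 2814 and 2548 (851 and 759 if independent, 6 opposite).

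Other lists were called lower with TG in knockdown cells. Of 77 ribosomal protein genes 53 fell in C4-2B and 53 in LNCaP (59 and 54 adjusted over the list alone; adjusted p = 6.57e-12 and 7.33e-09), with adjusted p = 0.292 with an estimated correlation and 0.434 likewise. Of 35 genes of oxidative phosphorylation 17 and 18 fell (21 and 19 adjusted over the list alone; adjusted p = 3.48e-05 and 0.000134), with adjusted p = 0.355 with an estimated correlation and 0.431 likewise. Of 16 heat shock genes 10 fell in C4-2B, and 10 fell and 1 rose in LNCaP (10, and 10 and 1, adjusted over the list alone; adjusted p = 2.07e-05 and 1.26e-05, and 0.00533 and 0.0164 with an estimated correlation). Of 24 G1/S genes 12 fell and 1 rose in C4-2B, and 13 fell and 1 rose in LNCaP (12 and 1, and 14 and 1, adjusted over the list alone; adjusted p = 0.00788 and 0.00154), with adjusted p = 0.488 with an estimated correlation in LNCaP and 0.0377 in C4-2B. Of 24 G2/M genes 12 fell and 1 rose in LNCaP (13 and 1 adjusted over the list alone; adjusted p = 0.00381, and adjusted p = 0.497 with an estimated correlation), and in C4-2B the adjusted p was 0.181. Of 17 NRF2 targets 8 fell and 2 rose in C4-2B (10 and 3 adjusted over the list alone; adjusted p = 0.0441, and adjusted p = 0.23 with an estimated correlation), a call lost without a filter on low counts (0.0653) and without siMOCOS TG replicate 2 (0.0805) or 3 (0.0655) or siMOCOS replicate 3 (0.0773) or 4 (0.0691). In LNCaP 14 of 24 hypoxia and glycolysis genes fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.501 with an estimated correlation), a call lost without siMOCOS TG replicate 2 (0.0614) or siMOCOS replicate 3 (0.0752) or 4 (0.051). There 6 of 12 genes of purine de novo synthesis fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.0472, and adjusted p = 0.124 with an estimated correlation), a call lost without siMOCOS TG replicate 2 (0.0524) or siMOCOS replicate 1 (0.0543) or 4 (0.0566). Of 14 luminal epithelium genes 5 fell and 3 rose in LNCaP (5 and 3 adjusted over the list alone; adjusted p = 0.0339, and adjusted p = 0.103 with an estimated correlation), a call lost without a filter on low counts (0.0697).

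As a list, genes of cholesterol synthesis had a higher response to TG in knockdown cells than in siCTRL cells. INSIG1 (chromosome 7, 155297776 to 155310235), which retains SCAP and SREBP in the ER and is itself an SREBP target, was at 391 ± 56.1 CPM in C4-2B siCTRL and 206 ± 24.7 with TG, and at 241 ± 16.1 in knockdown and 297 ± 36.8 with TG (SD, n = 4 each). Its interaction of knockdown and TG was log2 1.23 (SE 0.182, adjusted p = 0.0195). In LNCaP INSIG1 was at 110 ± 8.86 and 75.9 ± 3.49 CPM in siCTRL without and with TG, and at 78.3 ± 0.974 and 109 ± 16.4 CPM in knockdown (SD, n = 4 each), with an interaction of log2 1.02 (SE 0.141, adjusted p = 0.0149). SQLE (chromosome 8, 124998497 to 125022283), squalene epoxidase, was at 103 ± 13.3 and 57.9 ± 7.77 CPM in C4-2B siCTRL without and with TG, and at 79.0 ± 10.7 and 118 ± 21.4 CPM in knockdown, with an interaction of log2 1.40 (SE 0.213, adjusted p = 0.0195). Of 19 measured cholesterol synthesis genes, 2 were called in C4-2B and 1 in LNCaP (5 and 2 adjusted over the list alone). Camera called the list in C4-2B (adjusted p = 7.83e-14) and LNCaP (adjusted p = 3.92e-08), and with an estimated correlation the adjusted p was 0.000663 and 0.0184. For knockdown with TG 7 of these genes rose and 1 fell in C4-2B (7 and 1 adjusted over the list alone; adjusted p = 0.0524). In LNCaP 6 rose (7 adjusted over the list alone; adjusted p = 0.0345, and adjusted p = 0.232 with an estimated correlation), a call lost without siCTRL TG replicate 1 (0.0615), 2 (0.0546) or 4 (0.0741) or siMOCOS TG replicate 1 (0.0591) or 2 (0.0952). DDR2, a collagen receptor kinase (log2 -1.54, adjusted p = 0.0471), and RDH11, a retinol dehydrogenase (log2 -0.78, adjusted p = 0.0495), had a lower response to TG after knockdown in C4-2B. The INSIG1 call in C4-2B was lost without siCTRL TG replicate 2 (0.0524), siMOCOS TG replicate 2 (0.0653), siMOCOS replicate 1 (0.0537) or siMOCOS replicate 4 (0.056). In LNCaP it held without siCTRL replicates 2, 3 and 4, siMOCOS TG replicates 3 and 4, and siMOCOS replicate 1, and was lost without any of the other 10 libraries (0.0508 to 0.168). The SQLE call was lost without siCTRL TG replicates 1 (0.0659), 2 (0.0524) or 4 (0.075), siMOCOS TG replicate 2 (0.0653) or siMOCOS replicate 4 (0.0754). The DDR2 call held only without siCTRL replicates 2 and 4 and siCTRL TG replicate 1 (elsewhere up to 0.123), and the RDH11 call only without siCTRL replicates 1 and 4 (elsewhere up to 0.14).

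**Figure D2:**
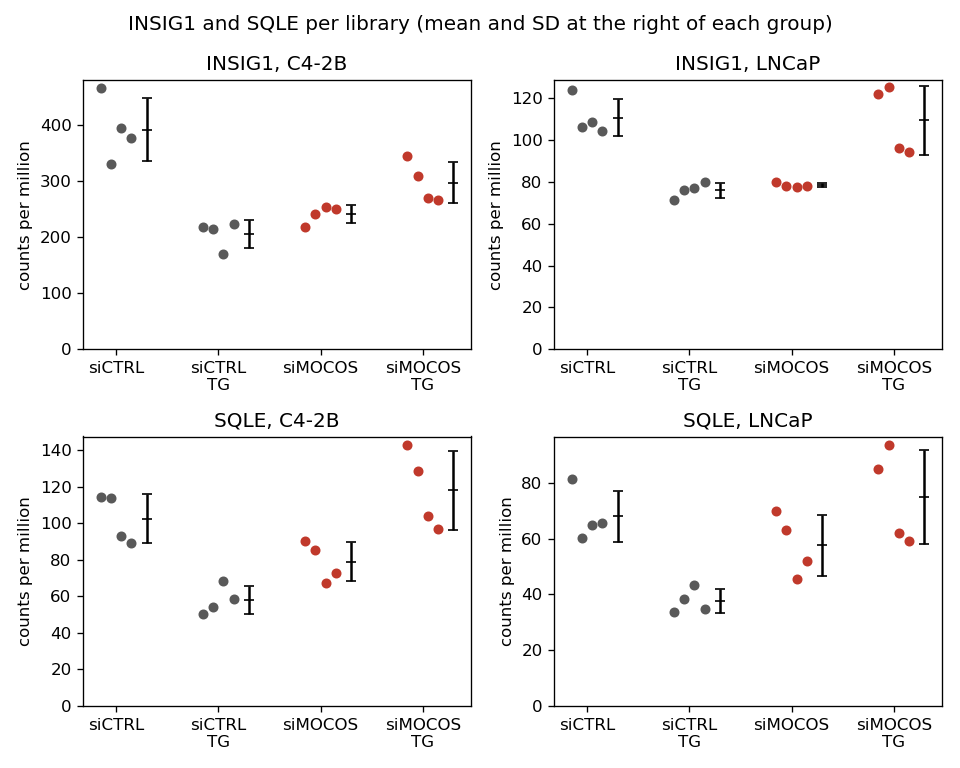
Level per library of INSIG1 (top) and SQLE (bottom), in CPM, for the 4 groups of C4-2B (left) and LNCaP (right), with the mean and SD of each group of 4 at the right of its points. INSIG1 in C4-2B has means of 391 and 206 CPM in siCTRL without and with TG, and of 241 and 297 CPM in knockdown.

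The interaction was called by edgeR for 4 genes higher and 6 lower in C4-2B and for 1 gene, INSIG1, in LNCaP, with 982 and 918 genes at an unadjusted p under 0.05. DESeq2 called 39 higher and 47 lower in C4-2B, and 31 and 24 in LNCaP. The GC and length correction gave 91 and 20 genes in the lines, the fit without the libraries that stand apart 5 and 0, and the fit of all libraries of both lines 44 in C4-2B. In C4-2B the count of 10 fell to between 1 and 6 when a single library was left out, except 11 without siCTRL replicate 4 and 7 without siMOCOS TG replicate 4, and was 1 without siCTRL TG replicate 2. Targets of the unfolded protein response had a positive interaction as lists over the pooled knockdown libraries, which does not show it in every library. For XBP1s the adjusted p was 5.08e-13 in C4-2B and 2.94e-05 in LNCaP, with adjusted p = 0.0541 with an estimated correlation and 0.524 likewise. For ATF6 it was 8.34e-08 and 0.00117, with adjusted p = 0.174 with an estimated correlation and 0.524 likewise. For PERK it was 5.68e-10 and 0.0468, with adjusted p = 0.174 with an estimated correlation and 0.55 likewise. No member of these lists was called over all genes, and 3, 3 and 7 in C4-2B and 0, 0 and 1 in LNCaP were called adjusted over the list alone. For knockdown with TG, camera did not call these lists in LNCaP (adjusted p = 0.669, 0.83 and 0.378 for XBP1s, ATF6 and PERK). Nor did it call PERK in C4-2B (0.353), where XBP1s and ATF6 were called higher as given above. The means not called were -0.0238, 0.0545 and -0.0943 in LNCaP and -0.143 for PERK in C4-2B. For knockdown without TG they were -0.283, -0.225, -0.227 and -0.503 in the same order. The ATF6 interaction call in LNCaP was lost without siMOCOS replicate 2 (0.0595). The PERK interaction call there was lost without any of 10 of the 16 libraries, up to 0.274 without siMOCOS TG replicate 4. In C4-2B the mean ATF6 interaction was 0.424, but the knockdown libraries were not alike. Without TG siMOCOS replicates 1 to 4 deviated from their group mean by -0.268, -0.203, 0.202 and 0.269. With TG they deviated by 0.193, 0.0874, -0.0977 and -0.182. In LNCaP the mean was 0.28. The deviations there were -0.277, -0.34, 0.314 and 0.303 without TG, and 0.00637, 0.0843, 0.00712 and -0.0978 with TG. For XBP1s the mean was 0.393 in C4-2B. Its deviations were -0.153, -0.124, 0.117 and 0.16 without TG, and 0.148, -0.0501, 0.046 and -0.144 with TG. In LNCaP the XBP1s mean was 0.259, with -0.165, -0.276, 0.187 and 0.254 without TG. With TG its deviations were -0.0672, 0.0287, 0.0449 and -0.00637. For PERK in C4-2B the mean was 0.36, with -0.283, -0.273, 0.26 and 0.296 without TG. With TG its deviations were -0.0758, -0.0671, 0.03 and 0.113. The p53 targets had a negative interaction in C4-2B (mean -0.335, adjusted p = 0.000114, and adjusted p = 0.0343 with an estimated correlation). In LNCaP it was negative too (adjusted p = 0.000246, and adjusted p = 0.182 with an estimated correlation). For this list C4-2B siMOCOS replicates 1 to 4 without TG deviated from their group mean by 0.185, 0.117, -0.0883 and -0.213. With TG they deviated by -0.0366, 0.00509, 0.0208 and 0.0107.

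Other lists had a positive interaction that was lost with an estimated correlation. The G2/M list, lower after knockdown in both lines, fell less with TG in C4-2B (mean 0.286, adjusted p = 7.78e-05, and adjusted p = 0.174 with an estimated correlation), with 0 genes called over all genes and 2 adjusted over the list alone. In LNCaP the adjusted p was 0.0889. Hypoxia and glycolysis was called in C4-2B (adjusted p = 0.0475, and adjusted p = 0.448 with an estimated correlation) and in LNCaP (adjusted p = 0.00383, and adjusted p = 0.524 with an estimated correlation), with 0 and 0 genes called over all genes and 1 and 1 adjusted over the list alone. The C4-2B call was lost without siCTRL replicate 3 (0.301) or 4 (0.159), siCTRL TG replicate 2 (0.07) or 4 (0.0859), siMOCOS TG replicate 4 (0.111), or siMOCOS replicate 1 (0.235) or 2 (0.0808), and the LNCaP call without siMOCOS replicate 2 (0.0925). Ribosomal proteins were called in LNCaP (adjusted p = 0.0352, and adjusted p = 0.782 with an estimated correlation), with 0 genes called over all genes and 0 adjusted over the list alone. That call was lost with the GC and length correction (0.061), without siCTRL replicate 2 (0.507) or 3 (0.0941), siCTRL TG replicate 1 (0.166), siMOCOS TG replicate 1 (0.638) or 2 (0.138), or siMOCOS replicate 1 (0.527) or 2 (0.106), and the list changed sign without siCTRL TG replicate 4 (0.784).

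Among genes that respond to TG, knockdown effects under TG were compared with the TG effect. Of the 5725 genes called with TG in C4-2B siCTRL cells, 52.4% had a knockdown effect of the opposite sign, and of the 6861 in LNCaP 59.9% did. Both effects share the siCTRL TG libraries, and data simulated without a knockdown effect gave 58.7% and 56.7%. With those libraries split 2 and 2 in all 6 ways, the share was 49.4% in C4-2B (47.3% to 51.6% over the splits; simulated 50%, from 48.8% to 50.8%). In LNCaP it was 57.5% (55.9% to 60.3%; simulated 50.2%, from 48.8% to 51.7%). The slope of the knockdown effect on the TG effect was -0.0703 in C4-2B and -0.0839 in LNCaP with shared libraries, and -0.0279 and -0.0424 with split libraries, where data simulated without a knockdown effect gave -0.0492 (-0.0674 to -0.0398) and -0.037 (-0.0505 to -0.0313) with shared libraries, and 0.00169 and 0.00218 with split libraries. These values are across genes, which are not independent replicates, and whether they differ between the lines was not tested. The simulated genes varied independently, without trends in GC content or length. In the data LNCaP siCTRL TG replicates 2 and 4 correlated with length at -0.457 and 0.468. The simulated ranges may thus be too narrow, and the gap to them in LNCaP does not establish an opposing knockdown effect.

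Untreated siCTRL cells of the lines differed in 3086 genes higher and 2941 lower in LNCaP than in C4-2B. HTATIP2, an oxidoreductase gene, had 1095 counts over the 4 LNCaP libraries and 0 over the 4 C4-2B libraries, so it was at least 379-fold higher in LNCaP. ECHDC1, an ethylmalonyl-CoA decarboxylase, had 808 and 0 counts and was at least 280-fold higher. ICAM1, a cell adhesion receptor, had 1226 counts in C4-2B and 2 in LNCaP. GALC, a lysosomal galactosylceramidase, was at 17.2 ± 3.92 CPM in C4-2B and 0.0620 ± 0.0479 in LNCaP (SD, n = 4 each; log2 -7.73, SE 0.467, adjusted p = 2.07e-14). XDH was higher in LNCaP (log2 1.34, SE 0.189, adjusted p = 1.23e-06). MOCOS was not called (log2 -0.37, SE 0.178, adjusted p = 0.0953), but was called when only the compared libraries were fitted (0.0131) and with the GC and length correction (0.00251).

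The response to TG differed between the lines for 61 genes with a higher and 63 with a lower response in LNCaP. CCDC80, a secreted matrix protein gene, went from 0.467 ± 0.145 to 6.62 ± 1.5 CPM with TG in LNCaP and was at 14.4 ± 3.05 and 12 ± 0.834 CPM in C4-2B (SD, n = 4 each), a difference of log2 4.02 (SE 0.471, adjusted p = 1.92e-05). RANBP3L, related to the Ran-binding protein RANBP3, was at 2.33 ± 0.478 and 8.65 ± 1.46 CPM in C4-2B without and with TG and at 14.4 ± 2.02 and 11.4 ± 1.30 CPM in LNCaP, a difference of log2 -2.24 (SE 0.364, adjusted p = 0.00115). The difference for GALC (log2 3.18, adjusted p = 0.0182) was lost without LNCaP siCTRL replicate 1 (0.0625) or 4 (0.0521). That for STC1, which encodes stanniocalcin 1 (log2 -2.26, adjusted p = 0.0212), was lost without C4-2B siCTRL replicate 2 (0.0516), LNCaP siCTRL replicate 3 (0.0514) or LNCaP siCTRL TG replicate 4 (0.0606). The difference for MOCOS was log2 0.48 (adjusted p = 0.566), and it was called when only the compared libraries were fitted (0.0401). The count of 124 was 65 with the replicate block, 225 with only the libraries compared, 280 with the GC and length correction, 72 without the libraries that stand apart, 78 without a filter on low counts, and 77 without LNCaP siCTRL replicate 3.

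The response to knockdown without TG differed between the lines for 3 genes higher and 20 lower in LNCaP. XDH differed by log2 -1.57 (SE 0.259, adjusted p = 0.00322). SLC22A3, an organic cation transporter, differed by log2 -2.25 (SE 0.335, adjusted p = 0.00191), at 0.900 ± 0.136 CPM in C4-2B siCTRL and 3.57 ± 0.166 in knockdown, and 90.8 ± 9.70 and 73.9 ± 20.9 CPM in LNCaP (SD, n = 4 each). UHRF1 differed by log2 1.11 (adjusted p = 0.0114). When only the compared libraries were fitted, the adjusted p was 0.118 for XDH and 0.0559 for UHRF1. The count of 23 was 35, 15, 11 and 11 without C4-2B siCTRL replicates 1 to 4, 15 and 13 without LNCaP siCTRL replicates 1 and 4, and 11 without LNCaP siMOCOS replicate 3. It was 90 with DESeq2, 80 with the GC and length correction, 12 without a filter on low counts and 6 with only the libraries compared. With TG 28 genes were higher and 35 lower, and with RLE factors 29 and 67. That count of 63 was 294 with DESeq2, 108 with limma voom, 108 with the GC and length correction, 15 without a filter on low counts, 9 without the libraries that stand apart and 1 with only the libraries compared. PLK2, a polo-like kinase, differed by log2 -1.44 (SE 0.175, adjusted p = 5.12e-05), at 11.1 ± 0.573 and 48.0 ± 2.38 CPM in C4-2B without and with knockdown, and 24.0 ± 2.28 and 38.1 ± 9.36 CPM in LNCaP. PHLDA1, a pleckstrin homology domain protein gene, differed by log2 2.25 (adjusted p = 0.0131, but 0.0594 without the libraries that stand apart and 0.0538 with only the compared libraries). The XDH difference with TG was log2 -0.67 (adjusted p = 0.138, and 0.0135 with DESeq2). The count of 63 ranged from 9 without LNCaP siCTRL TG replicate 4 to 172 without C4-2B siMOCOS TG replicate 2, and stayed near it (60 and 84) only without C4-2B siCTRL TG replicate 3 or LNCaP siMOCOS TG replicate 3.

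Purine salvage and pyrimidine genes were called lower by camera with TG in siCTRL cells of both lines, and purine de novo synthesis in LNCaP, and each of these calls was lost with an estimated correlation. Of 7 purine salvage genes 3 fell in C4-2B and 3 in LNCaP (4 and 4 adjusted over the list alone; adjusted p = 0.0154 and 0.0377), with adjusted p = 0.211 with an estimated correlation and 0.129 likewise. These calls were lost without C4-2B siCTRL TG replicate 3 (0.052) and LNCaP siCTRL TG replicate 4 (0.069). Of 12 genes of purine de novo synthesis 8 fell and 1 rose in LNCaP (9 and 1 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.0699 with an estimated correlation), and in C4-2B the adjusted p was 0.0594. Of 14 genes of pyrimidine synthesis and catabolism 5 fell and 1 rose in C4-2B (5 and 1 adjusted over the list alone; adjusted p = 0.0423, and adjusted p = 0.211 with an estimated correlation), a call lost without siCTRL replicate 4 (0.0601) or siCTRL TG replicate 3 (0.0953). In LNCaP 8 fell (8 adjusted over the list alone; adjusted p = 0.0222, and adjusted p = 0.282 with an estimated correlation). Of 24 hypoxia and glycolysis genes 14 fell and 2 rose in C4-2B and 17 fell and 2 rose in LNCaP (15 and 2, and 17 and 2, adjusted over the list alone). The adjusted p was 0.00475 and 0.000778, with adjusted p = 0.19 with an estimated correlation and 0.282 likewise.

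Of 17 NRF2 targets measured in C4-2B, 11 fell with TG (11 adjusted over the list alone, adjusted p = 0.0154, and adjusted p = 0.183 with an estimated correlation). Of 19 measured in LNCaP, 6 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.513). The LNCaP median was -0.0666 and the mean 0.0136. Of 20 p53 targets 10 rose and 3 fell in LNCaP (10 and 3 adjusted over the list alone; adjusted p = 0.0296, and adjusted p = 0.282 with an estimated correlation), and in C4-2B the adjusted p was 0.203. Of 14 luminal epithelium genes 6 fell and 1 rose with TG in C4-2B, and 7 fell and 2 rose in LNCaP (7 and 1, and 7 and 2, adjusted over the list alone). The list was called lower, with adjusted p = 0.0242 in C4-2B and 0.011 in LNCaP, and adjusted p = 0.102 with an estimated correlation and 0.0679 likewise. With TG in siCTRL cells the lists of cholesterol synthesis (adjusted p = 0.692 in C4-2B and 0.147 in LNCaP), interferon response (0.756 and 0.378), autophagy and lysosome (0.47 and 0.773), basal and mesenchymal markers (0.432 and 0.657), neuroendocrine markers (0.0902 and 0.773) and immune, stromal, endothelial and blood markers (0.189 and 0.418) were not called. Median and mean differed in sign for cholesterol synthesis in C4-2B (0.00868 and -0.01) and, in LNCaP, for interferon response (-0.00428 and 0.264), autophagy and lysosome (-0.17 and 0.0674) and basal and mesenchymal markers (-0.00696 and 1.04).

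**Figure D3:**
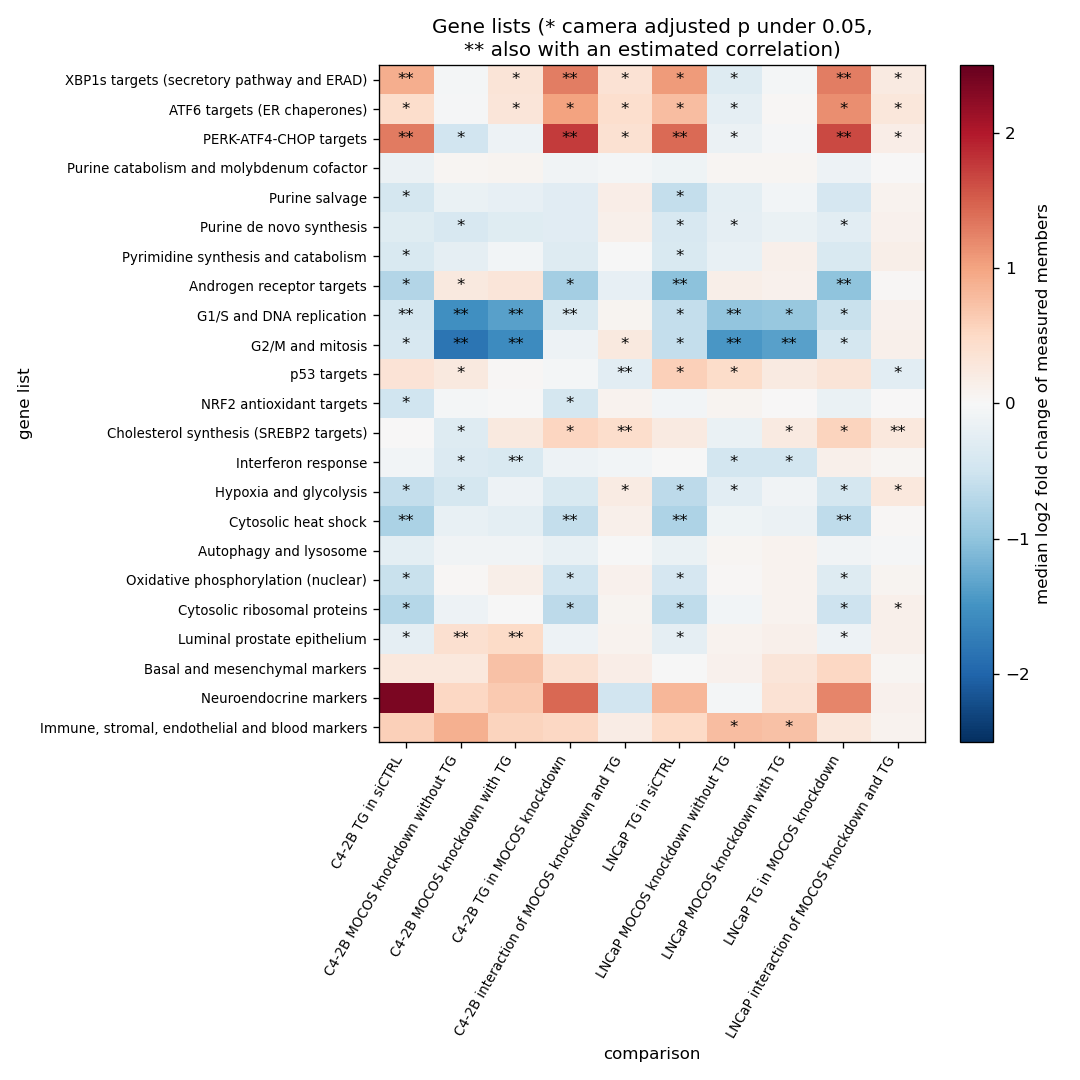
Median log2 fold change of the measured members of each gene list, as colour, for the 10 comparisons within a line, with * for a camera adjusted p under 0.05 and ** where this also holds with an estimated correlation. The G2/M list has a median of -1.83 for C4-2B and -1.46 for LNCaP knockdown without TG.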

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

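Single libraries were compared with the other 3 of their group by a Dixon test, for the genes picked for the text. Of 522 groups tested 20 passed it, where chance alone gives about 1 in 20, or 26.1, so their total does not exceed chance. Genes of a library are not independent, and this total does not cover how the flagged values gather in single libraries.

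In C4-2B siCTRL TG replicate 3, a library whose deviations correlated with transcript length, 6 genes passed. ASNS was at 350 CPM (558 to 585 in the other 3), COX7B at 51.3 CPM (72.8 to 76.1) and INSIG1 at 169 CPM (214 to 223). MCM4 was at 256 CPM (192 to 195), MCM3 at 142 CPM (122 to 123) and STEAP2 at 527 CPM (400 to 413). In C4-2B siCTRL replicate 1 HSPA8 was at 4340 CPM (3450 to 3510), MCM7 at 287 CPM (295 to 296) and ICAM1 at 17.3 CPM (23.5 to 23.8). In C4-2B siMOCOS replicate 4 RPL24 was at 624 CPM (657 to 662) and CHAC1 at 2.29 CPM (0.862 to 1.04). In C4-2B siCTRL TG replicate 4 OASL was at 4.41 CPM (5.77 to 5.96).

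In LNCaP siCTRL replicate 4 LAMP3 was at 1.15 CPM (0.484 to 0.568), CCNA2 at 49.9 CPM (37.6 to 39.2) and ECHDC1 at 10.1 CPM (14.1 to 14.4). KRT80 in LNCaP siCTRL replicate 3 was at 0.568 CPM (0.17 to 0.215). With TG, LNCaP siCTRL replicate 2 had OASL at 12 CPM (7.95 to 8.64), replicate 3 had ECHDC1 at 17.1 CPM (12.1 to 12.8) and replicate 4 had ESCO2 at 37.1 CPM (28 to 29). STARD4 in LNCaP siMOCOS TG replicate 2 was at 132 CPM (115 to 118). The cause of these values was not tested.

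Effects that differed between groups are listed with their log2 size. Between the lines the TG response differed for CCDC80 (4.02), GALC (3.18), STC1 (-2.26) and RANBP3L (-2.24). The knockdown response without TG differed for UHRF1 (1.11), SLC22A3 (-2.25) and XDH (-1.57), and with TG for PHLDA1 (2.25) and PLK2 (-1.44). The TG response differed after knockdown in C4-2B for SQLE (1.40), INSIG1 (1.23), DDR2 (-1.54) and RDH11 (-0.78), and in LNCaP for INSIG1 (1.02).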

How the results depend on the processing

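Counts and named values were computed again under the alternatives that could be run for them, and those that moved are given here by setting. The replicate block was run for TG in siCTRL, the untreated lines and the line difference in TG response, the fit of all libraries for comparisons within a line, and the fit of only the libraries compared for all but the interactions. The correction for GC content and length and the fit without the libraries that stand apart were chosen after the data were seen. Of the gene values 1926 stayed the same when a library was left out, 84 lost their call and 6 gained one, and 69 list calls were lost with an estimated correlation. The cause of the shifts was not tested.

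With a change of at least 1 log2 unit required, C4-2B kept 2140 genes for TG in siCTRL, 971 and 895 for knockdown without and with TG, and 1963 for TG in knockdown. LNCaP kept 2299, 470, 612 and 2111 in the same order. The lines kept 2323 without TG, 70 for the TG response, and 12 and 29 for the knockdown response without and with TG.

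DESeq2 called 86 genes for the interaction in C4-2B and 55 in LNCaP, and 90 and 294 for the line difference in knockdown response without and with TG. It gave no adjusted p for 4 named values. Limma voom called 6 for the C4-2B interaction and 108 for the line difference in knockdown response with TG. RLE factors gave 96 for that difference. Without a filter the C4-2B interaction had 6 genes, and the line differences 78 (TG response), 12 and 15 (knockdown response without and with TG). Without rounding the C4-2B interaction had 6 genes, and with all libraries of both lines 44.

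With the GC and length correction the interaction had 91 genes in C4-2B and 20 in LNCaP, and the line differences 280 (TG response), 80 and 108 (knockdown response without and with TG). The MOCOS difference between untreated lines was then -0.627. Without the libraries that stand apart the interaction had 5 and 0 genes, the line difference in TG response 72 and that in knockdown response with TG 9. Cytosolic ribosomal proteins in LNCaP interaction of MOCOS knockdown and TG changed sign as a list (adjusted p = 0.784), as it did without LNCaP siCTRL TG replicate 4 alone (0.784), and its adjusted p was lowest without LNCaP siCTRL TG replicate 2 (0.000125).

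With only the libraries compared the line differences had 225 (TG response), 6 and 1 genes (knockdown response without and with TG). MOCOS was then called between untreated lines (-0.383) and for the TG response (0.475). With the replicate block on siCTRL libraries, TG called 4960 genes in C4-2B and 6543 in LNCaP, the untreated lines differed in 5654, and the line difference in TG response had 65. No paired analysis was possible because the knockdown columns carry no replicate number of the labels, so the block was fitted for siCTRL libraries alone. Neither the agreement of the siRNAs nor each siRNA alone could be run.

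With the siCTRL TG libraries split 2 and 2, 49.4% of the TG-responsive genes in C4-2B had an opposite knockdown effect, and the slopes were -0.0279 in C4-2B and -0.0424 in LNCaP. With each library left out in turn the counts ranged from 1 to 11 for the C4-2B interaction, 0 to 1 for the LNCaP interaction, 1392 to 2129 for LNCaP knockdown without TG and 1925 to 3454 with TG. The line differences ranged from 77 to 113 for the TG response, and from 11 to 35 and 9 to 172 for the knockdown response without and with TG.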

Other observations

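The test that counts knockdown libraries below all siCTRL libraries was chosen after the result was seen, and the other tests in this part were written down before their own results were seen. The correction for GC content and length and the 3 libraries that stand apart were themselves chosen after the data were seen, and these 3 were taken for positive correlations with length alone. Each test gives the smallest remaining effect against its SE, among the lists and comparisons of the pattern.

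The means of the G2/M and G1/S lists were lower after MOCOS knockdown in both lines, with and without TG. The smallest effect, G1/S in LNCaP with TG, lost its camera call (adjusted p = 0.0508 with an estimated correlation). It was -0.842 in mean log2 CPM per library. After correction for GC content and length it stayed at -0.86 (SE 0.135), and at -0.868 (SE 0.13) with every library thinned to the smallest total. The knockdown libraries behind it were not alike. Here siMOCOS TG replicates 1 to 4 deviated from their group mean by 0.223, 0.143, -0.178 and -0.188. For G2/M in LNCaP without TG, siMOCOS replicates 1 to 4 deviated by 0.375, 0.2, -0.266 and -0.309. The G2/M mean lay below all siCTRL libraries of the same line and drug in 16 of 16 knockdown libraries. For both lists the corrections argue against GC content or depth as the whole cause, and against length as far as the longest transcript stands for it. The count argues against a few libraries for G2/M, and it was not made for G1/S. Slower cycling of MOCOS-depleted cells may explain the pattern, which a count of cells in S phase could test. With 2 libraries of each siRNA in a knockdown group per the labels, 16 of 16 also argues against an effect of only 1 of the siRNAs on G2/M genes, and an effect outside MOCOS that both share stays open.

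The mean response of the cholesterol synthesis list to TG was higher in knockdown cells. In LNCaP, where it was smallest, the difference was 0.363 (SE 0.0691), and it stayed at 0.303 (SE 0.0605) after the GC and length correction, 0.289 (SE 0.0701) with thinned libraries and 0.328 (SE 0.0647) without the libraries that stand apart. In C4-2B camera also called the list lower after knockdown without TG (mean -0.283, adjusted p = 0.0273, and 0.0547 without siCTRL replicate 1). That call was lost with an estimated correlation (adjusted p = 0.161), and in LNCaP the list was not called (mean -0.125, adjusted p = 0.314). With TG its mean change after knockdown was 0.231 in C4-2B and 0.238 in LNCaP, so where the interaction arises is left open. A change in SREBP2 processing after MOCOS loss may explain it, and SREBP2 cleavage in the 4 groups would test this. The single calls behind it depend on 1 library in many cases.

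The means of the ribosomal protein and oxidative phosphorylation lists were lower with TG. The effect stayed at -0.491 (SE 0.111) after the GC and length correction and -0.545 (SE 0.163) with thinned libraries for oxidative phosphorylation in C4-2B knockdown cells, and was -0.726 (SE 0.165) without the libraries that stand apart for ribosomal proteins in C4-2B siCTRL cells. For ribosomal proteins in siCTRL cells the GC and length correction moved it from -0.745 to -0.673 (SE 0.121) in C4-2B and from -0.656 to -0.591 (SE 0.0844) in LNCaP. Leaving out the libraries that stand apart moved oxidative phosphorylation in LNCaP siCTRL cells from -0.492 to -0.391 (SE 0.0663). These values argue against GC content, depth or those 3 libraries as the whole cause. The length used was that of the longest annotated transcript of a gene, which need not be the one expressed. A trend with the expressed length thus stays open. Camera lost these lists with an estimated correlation. The SE here is that of list means per library, so it already holds co-variation of the members within groups. The effects thus argue against such co-variation as the whole cause. Co-variation that differs between the groups stays open.

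Other splits of the libraries were set beside the real grouping by their number of called genes. In C4-2B the real grouping was the highest of 35 splits, 1 of 35, for TG in siCTRL (5725 genes; highest other 1), knockdown without TG (2434; 1), knockdown with TG (2375; 1) and TG in knockdown (5360; 1687). In LNCaP it was also 1 of 35 for TG in siCTRL (6861; 0), knockdown without TG (2173; 0), knockdown with TG (3025; 1) and TG in knockdown (6485; 1509). For the interaction 3 of 50 splits in C4-2B called at least the real 10 (highest 1266), and in LNCaP 2 of 50 called at least the real 1 (highest 514). The splits between the lines were fitted with only the libraries compared, where the real grouping called 5917 genes for the untreated lines, 225 for the TG response, and 6 and 1 for the knockdown response without and with TG. The fit of all libraries, which the report uses, called 6027, 124, 23 and 63, and no splits were run for it. In the smaller fit the real grouping was 1 of 35 for the untreated lines (highest other 0). For the TG response 3 of 50 splits called at least as many genes (highest 5459), and for the knockdown response 2 of 50 without TG (highest 691) and 2 of 50 with TG (highest 68). These splits exchange libraries across a real effect of TG or knockdown, so whether chance can be excluded for the interactions and the line differences in response cannot be read from them.

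A split that calls many genes points to a structure of the samples. The splits with 1687 genes in C4-2B and 1509 in LNCaP both set knockdown columns 1 and 2 against 3 and 4, with and without TG. Such a structure could come from the 2 siRNAs, but this was not tested and no column was assigned to an siRNA. The pooled knockdown groups thus hold a difference between their libraries that the edgeR dispersion takes as replicate variation. In the interactions the highest splits had 6 of the libraries with TG exchanged between siCTRL and siMOCOS and none without TG, so they carry part of the knockdown effect. The split with 5459 genes had 6 LNCaP libraries exchanged between TG and no TG and none in C4-2B, so it carries the TG effect.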
